A study of Homo sapiens with 23 samples.

How the data were processed

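RNA from human colon biopsies was measured on 23 microarrays, 11 REF, 8 UC and 4 Internal Control. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with an RNeasy Plus Mini kit, amplified with a TargetAmp kit and labelled with biotin. Per the submitters' processing notes, RMA was used, with no version given. The array type, the probe set definition and the batch of each REF and UC array are not given in the sources used here.

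The deposited table holds 26121 probe sets named by RefSeq accession. Its values are linear ratios: the deposited ratio of each probe set has an arithmetic mean over the REF arrays between 1.0 and 1.0027, and the Internal Control columns differ by at most 2.4e-07 of their value. Per the labels' series text, the Internal Control arrays of batches 1, 2, 4 and 5 were used by the authors to normalize the values. The lowest deposited ratio is 0.01 and the highest is 310, and 38 values in 12 probe sets stood at the lower limit in the REF and UC arrays. A ratio carries no level or depth, so dim probe sets could not be recognised. The number of arrays limits the precision. Because each REF mean is set to 1 on the linear scale, the mean log2 value of REF lies below 0 where the REF arrays vary. Differences between groups are not affected by that scaling. None of the 171 pairs of REF and UC arrays held identical values.

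Ratios were transformed to log2 with no pseudocount. Accessions were matched to symbols through a RefSeq gene table of assembly GRCh38.p14, used for names only. In all, 20443 probe sets matched 1 symbol, 0 several and 5678 none, of which most were among the 3864 model (XM) accessions. For human samples XIST and Y-linked genes were left out (39 probe sets), which left 26082 probe sets. For tests of genes, 1 probe set per gene was used, the one with the largest variance over the REF and UC arrays without regard to group, since a mean of ratios carries no level. This gave 15948 genes.

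UC was compared with REF by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over the REF and UC arrays without covariates, two-sided, with Benjamini-Hochberg adjustment over all probe sets or genes and a threshold of 0.05. Folds are UC over REF on the log2 scale with limma's standard error. A limit of 2-fold was applied as a further count. The 35 gene lists, with 555 genes of which 518 had a probe set, covered inflammation, stroma, immune and epithelial cell types, metabolism, stress, barrier, colon segment and RNA handling. They were tested with limma's camera with a preset correlation of 0.01, with camera with an estimated correlation, and with fry. Fry's p tests whether a list's genes move on balance one way and compares it with no other genes. Mean scores of gene sets were compared by linear regression on group, with and without PRAC1. Data preparation and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

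Genes named in the text are the 6 highest and 6 lowest log2 fold changes among genes past the test (no open reading frame, LOC or clone names), and from each list the member with the smallest p, with the next for lists past the test. Results that rest on certain genes, among them another covariate for colon segment, tried before PRAC1, with which fewer genes passed than with PRAC1, are not reported here. Genes named otherwise are said to be chosen after their values were seen. The lists, the naming rule, the tests and the first set of alternatives were fixed before the data were examined.

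The alternatives were quantile normalization, centring of each array on its median, a trended and robust variance prior, array weights, the replicate number as a block, each array left out in turn, only the probe sets or genes of higher variance, an exact Wilcoxon rank-sum test, a 1.5-fold limit, the mean of a gene's probe sets, and lists without shared genes. Added after seeing the data were REF 4, 5 and 6 left out, REF 7, 8 and 9 left out, the log2 ratio of PRAC1 as a covariate, and the arrays numbered 1 to 8 without the block. REF 4, 5 and 6 correlated most with the UC mean and REF 7, 8 and 9 least. Leaving them out therefore tends to raise and to lower differences, respectively, by the choice itself.

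The tests were tested on simulated data for UC against REF with the real array numbers and 26082 probe sets. Of 100 probe sets changed by log2 1 limma recovered 80, of 100 changed by log2 2 it recovered 96, and 9 others were called. The exact Wilcoxon test recovered 75 and 94, with 8 others called. For the list test, run on 15948 simulated genes, camera called 3 of 3 raised lists and 0 of 31 lists without a raised member. The simulated noise was drawn independently for each probe set, with the same spread in both groups. These counts therefore do not show how often camera errs where genes are correlated, as they are in the real arrays. Far fewer probe sets were changed in the simulation than the 50.5% called in the real arrays. The adjusted threshold depends on that share, so the recovery may differ in the real data.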

Results

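Gene expression was measured on microarrays in human colon biopsies. The series holds 23 arrays: 11 labelled REF, 8 labelled UC and 4 labelled Internal Control. The series text names biopsies of UC taken at diagnosis, from the most proximal affected part of the colon, and biopsies of healthy controls. The labels do not spell out UC. REF is taken as the healthy controls because it is the only other colon group. The 4 Internal Control arrays, which the series text says served to normalize the values, were not compared as a group. Each value is a linear ratio without a depth, and the number of arrays limits the precision. Nothing in the labels says more than that the REF and UC arrays are separate samples, so p-values measure the spread between these samples. The colon segment of the REF biopsies and the processing batch of each REF and UC array are not given in the sources used here.

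The comparison of UC with REF asks how expression differs between biopsies of UC colon and of healthy colon. In UC, SLC6A14, DUOX2 and 4 matrix metalloproteinases had the largest increases, and AQP8, MEP1B, PCK1, HSD3B2 and SLC51A were among the largest decreases. SLC6A14, an amino acid transporter, was 118-fold higher (log2 fold change 6.88 ± 0.78 SE, adjusted p = 4.51e-06) and lay above every REF array in 7 of 8 UC arrays. The matrix metalloproteinases MMP3, MMP10, MMP1 and MMP7 were higher by log2 6.21 ± 0.61, 5.75 ± 0.64, 5.62 ± 0.66 and 5.06 ± 0.72, with 7 of 8 UC arrays above every REF array for MMP3 and MMP7. Without UC 1 SLC6A14 was higher by 7.77, MMP3 by 6.89, MMP10 by 6.50 and MMP7 by 5.80. DUOX2, an oxidase of the epithelium that makes hydrogen peroxide, was 72.8-fold higher (log2 6.19 ± 0.56) and lay above every REF array in 8 of 8 UC arrays. At the other end, AQP8, a water channel of colonocytes, fell by 5.43 ± 0.50 on the log2 scale, and PCK1, an enzyme of gluconeogenesis, fell by 5.22 ± 0.45. The metalloprotease MEP1B fell by 5.22 ± 0.58 and the steroid dehydrogenase HSD3B2 fell by 4.86 ± 0.77, and with REF 4, 5 and 6 left out it fell by 5.56. SLC51A, a subunit of the basolateral bile acid exporter, fell by 4.28 ± 0.81. The deposited ratio stood at its lower limit, 0.01, in 4 UC arrays for AQP8, 3 for MEP1B, 1 for PCK1, 5 for HSD3B2 and 4 for SLC51A, so the true ratio of those arrays is not known. With PRAC1, a distal colon marker, as a covariate, chosen after seeing the data, MEP1B fell by 3.72 ± 0.45, HSD3B2 by 2.95 ± 0.63 and SLC51A by 2.26 ± 0.66, and SLC6A14 and MMP7 were higher by 6.20 and 4.08. With quantile normalization SLC6A14 was higher by 4.12, DUOX2 by 4.03, MMP3 by 3.81, MMP1 by 3.54, MMP10 by 3.33 and MMP7 by 3.16. AQP8, MEP1B, PCK1, HSD3B2 and SLC51A stood at -4.64, -4.64, -4.12, -3.94 and -3.54 with it, and 38 of 64 named genes had a fold smaller by over 1.5 times.

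In all, 8206 of 15948 genes (51.5%) passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 3077 of them higher and 5129 lower in UC. At the level of probe sets, 13183 of 26082 passed, 4584 higher and 8599 lower, and 2833 of these differed at least 2-fold, 1657 higher and 1176 lower. For 544 genes all UC arrays lay above all REF arrays, and for 500 all lay below, where chance gives 0.0013% of genes on each side. The median log2 fold change over all genes was -0.11 as deposited and 0.01 after each array was centred on its median. Relative to the median gene, each log2 value given here is therefore 0.11 higher. After that centring 4080 genes were higher and 3415 lower (45.6% lower, against 62.5% as deposited). Among probe sets it gave 6088 higher and 5636 lower, and 1955 higher and 914 lower at 2-fold. Quantile normalization reduced the counts to 3279 genes (1718 higher, 1561 lower), 4929 probe sets (2538 higher, 2391 lower) and 1206 at 2-fold. With the log2 ratio of PRAC1 as a covariate they were 4899, 7684 and 2351. PRAC1 is the milder of 2 covariates for colon segment that were tried, the one with which more genes passed. Under it a median of 91.2% of the log2 fold change remained over the genes called without it, the median standard error rose from 0.14 to 0.17, and 8204 of 8205 genes kept their direction. Of 63 named genes 59 kept their call with it, and 4, BANK1, PAX5, ISL1 and BUB1, lost it with the same direction. Quantile normalization ended the calls of 6 named genes, OAS2, BANK1, PAX5, SCG5, BUB1 and PRAC1.

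**Figure D1:**
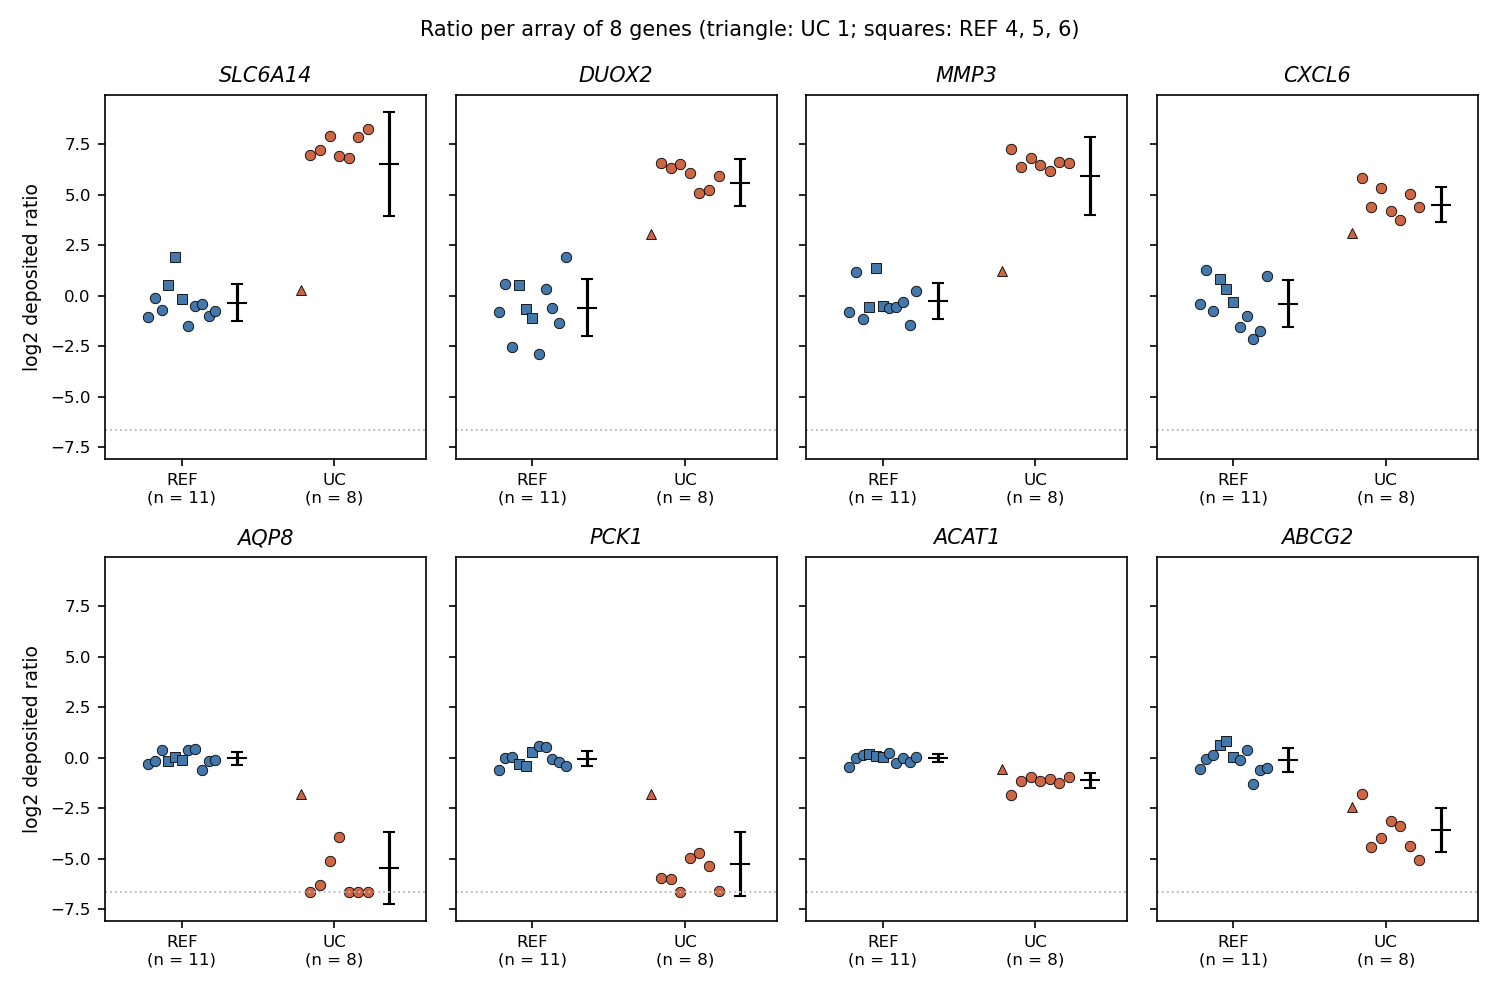
Deposited ratio per array on a log2 axis for 8 genes, as points for REF (blue, n = 11) and UC (orange, n = 8), with the group mean and SD beside them; the dotted line is the lower limit of the values, triangles are UC 1 and squares are REF 4, 5 and 6. UC 1 lay at 0.27 for SLC6A14 and 1.21 for MMP3, where the other UC arrays lay between 6.81 and 8.27 and between 6.16 and 7.27.

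Genes of neutrophils and of their recruitment rose. All 7 measured CXC chemokines that attract neutrophils passed the gene test upward, with a median log2 fold change of 3.90 and with CXCL6 (4.91 ± 0.46 SE) and CXCL5 (4.77 ± 0.45) at the smallest p. Of 15 neutrophil markers 14 were higher and 1 did not pass, with a median of 2.66. S100A9, a subunit of calprotectin, was higher by 3.07 ± 0.42 and the chemokine receptor CXCR2 by 2.74 ± 0.39. Blood carries neutrophils and red cells alike, and globins rose too (HBA1 and HBA2 above every REF array in 8 of 8 UC arrays), so neutrophils in blood and in tissue are not separated here. Of 20 cytokines 10 were higher, 1 was lower and 9 did not pass, among them IL6 (2.25 ± 0.27) and IFNG (1.82 ± 0.25) upward. Adjusted over the list alone, 11 were higher and 1 lower. Genes of the IL6 and STAT3 response gave 12 higher, 1 lower and 12 not past, with the kinase PIM2 at 2.66 ± 0.28 and the adhesion molecule ICAM1 at 1.63 ± 0.17. By camera, which compares a list with all other genes, these 4 lists were shifted upward (adjusted p = 3.43e-08, 6.78e-09, 5.76e-06 and 7.73e-07 in the order given). None held when the correlation within each list was estimated: adjusted p = 0.117, 0.118, 0.127 and 0.117 with an estimated correlation.

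Interferon gamma response genes rose, whereas those of type I interferon moved both ways in the values as deposited. Of 14 measured genes of the gamma response 11 were higher, 1 was lower and 2 did not pass, and the list was shifted upward (camera adjusted p = 3.16e-07; adjusted p = 0.117 with an estimated correlation). Adjusted over the list alone, 12 were higher and 1 lower. WARS1, a tryptophanyl-tRNA synthetase, was higher by 1.92 ± 0.16 and the chemokine CXCL11 by 4.35 ± 0.53. Of 18 type I interferon genes 5 were higher, 4 were lower and 9 did not pass, and the list did not pass camera (adjusted p = 0.34). After median centring 6 were higher and 2 lower, and after quantile normalization 0 and 0. Its median (-0.08) and mean (-0.01) lay below 0 while camera's direction was upward, and the median turned to 0.04 after median centring. OAS2, an antiviral oligoadenylate synthetase, rose by 1.62 ± 0.30, a call lost with quantile normalization (adjusted p = 0.063). Complement genes gave 15 higher of 16, or 9 with quantile normalization (camera adjusted p = 6.78e-09 as deposited, and adjusted p = 0.117 with an estimated correlation). C4BPB, the beta chain of C4b-binding protein, was higher by 3.36 ± 0.39 and the C1 inhibitor gene SERPING1 by 2.15 ± 0.27.

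Antimicrobial and acute response genes of the epithelium rose in 14 of 18 cases, with a median of 2.94. The list was shifted upward (camera adjusted p = 4.23e-10; adjusted p = 0.117 with an estimated correlation). Besides DUOX2, the acute-phase gene SAA1 had the smallest p, higher by 2.93 ± 0.26 in UC and above every REF array in 8 of 8 UC arrays. Of 7 Paneth cell markers 2 were higher and 5 did not pass, and the list did not pass (adjusted p = 0.15). Its leading member, the lysozyme gene LYZ, which macrophages also express, rose by 2.49 ± 0.64 (3.31 with REF 4, 5 and 6 left out, 1.57 with REF 7, 8 and 9 left out). With PRAC1 as a covariate the Paneth cell list was called upward (adjusted p = 0.036; adjusted p = 0.26 with an estimated correlation).

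Stromal genes of the matrix rose, and those of smooth muscle and glia did not move as a list. Of 17 matrix proteases and inhibitors 14 were higher, with a median of 1.98 (camera adjusted p = 1.76e-09; adjusted p = 0.117 with an estimated correlation). Besides the metalloproteinases above, TIMP1, their tissue inhibitor, was higher by 3.47 ± 0.33. Of 21 fibroblast and collagen genes 20 were higher over all genes and 21 adjusted over the list alone, with a median of 2.06 (camera adjusted p = 7.33e-14; adjusted p = 0.117 with an estimated correlation). The glycoproteins PDPN and TNC were higher by 2.29 ± 0.22 and 3.63 ± 0.37, each above every REF array in 8 of 8 UC arrays. Of 17 endothelial markers 12 were higher, with the adhesion molecules SELP at 1.85 ± 0.25 and PECAM1 at 1.77 ± 0.24 (camera adjusted p = 4.13e-07; adjusted p = 0.137 with an estimated correlation). Of 12 smooth muscle and enteric glia markers 1 was higher, 3 were lower and 8 did not pass, and the list did not pass (adjusted p = 0.86). The median (-0.01, but 0.11 after median centring and 0.04 after quantile normalization) and mean (-0.13) of this list lay below 0 while camera's direction was upward.

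Markers of most immune cell types were higher, those of plasma cells without exception. All 9 measured plasma cell markers rose, with a median of 2.05, MZB1 at 2.53 ± 0.22 and FKBP11 at 2.71 ± 0.26 (camera adjusted p = 6.70e-08; adjusted p = 0.117 with an estimated correlation). Of 17 T cell markers 13 were higher and 4 did not pass, 14 being higher adjusted over the list alone, with the costimulatory receptor ICOS at 2.31 ± 0.37 and CD2 at 1.71 ± 0.35 (camera adjusted p = 6.58e-07; adjusted p = 0.213 with an estimated correlation). Of 14 monocyte and macrophage markers 11 were higher, with CD86 at 1.90 ± 0.35 and CD14 at 1.32 ± 0.26 (camera adjusted p = 7.58e-05; adjusted p = 0.219 with an estimated correlation). Of 14 mast cell and eosinophil markers 4 were higher, 2 were lower and 8 did not pass. The 2 with the smallest p were both mast cell genes, the histamine-forming enzyme HDC at 1.27 ± 0.18 and the carboxypeptidase CPA3 at 4.13 ± 0.92, or 5.32 with REF 4, 5 and 6 left out, 3.00 with REF 7, 8 and 9 left out and 3.29 over numbers 1 to 8 (camera adjusted p = 0.021; adjusted p = 0.40 with an estimated correlation). Of 13 B cell markers 4 were higher, 1 was lower and 8 did not pass, or 2 and 1 adjusted over the list alone. BANK1 was higher by 2.21 ± 0.56 (1.54 with PRAC1 as a covariate, 2.80 with REF 4, 5 and 6 left out and 1.56 with REF 7, 8 and 9 left out) and PAX5 fell by 0.35 ± 0.10. The B cell list passed camera (adjusted p = 0.018; adjusted p = 0.44 with an estimated correlation) but not after quantile normalization (adjusted p = 0.076), median centring (adjusted p = 0.059) or without REF 7, 8 and 9 (adjusted p = 0.065), nor by fry (adjusted p = 0.10). With PRAC1 as a covariate the B cell list (adjusted p = 0.23) and the mast cell list (adjusted p = 0.0515) were not called. With quantile normalization fewer members of these lists passed upward. They were 7 plasma cell, 5 T cell, 3 monocyte and macrophage, 3 mast cell and eosinophil and 0 B cell markers. Unfolded protein response genes, active in secretory cells, rose in 16 of 19 cases, with EDEM1 at 0.84 ± 0.10 and SEL1L at 1.09 ± 0.16 (camera adjusted p = 6.78e-09; adjusted p = 0.117 with an estimated correlation).

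Absorptive colonocyte genes and genes of oxidation and detoxification fell. Whether these falls reflect a lower share of epithelium in the biopsies or a change within cells was not tested. Of 24 absorptive colonocyte genes 21 were lower, 3 did not pass and the median was -1.40, with PCK1 and AQP8 at the smallest p. Of 21 genes of butyrate uptake and fatty acid oxidation, the main fuel route of colonocytes, 20 were lower and the median was -1.10. The mitochondrial thiolase ACAT1 fell by 1.10 ± 0.13. Of 25 respiratory chain and citrate cycle genes 24 were lower over all genes and 25 adjusted over the list alone, by a smaller median of -0.58. SDHB, a subunit of succinate dehydrogenase, fell by 0.84 ± 0.12 and the citrate synthase gene CS by 1.07 ± 0.16. Of 19 xenobiotic transport and detoxification genes 16 were lower, with the carboxylesterase CES2 down by 1.76 ± 0.19 and the efflux pump ABCG2 down by 3.46 ± 0.37. Camera found these 4 lists shifted downward (adjusted p = 3.43e-08, 1.76e-09, 7.47e-08 and 6.63e-06). With an estimated correlation the calls were lost (adjusted p = 0.130, 0.123, 0.219 and 0.117 with an estimated correlation). Hypoxia and glycolysis genes gave 9 higher, 1 lower and 6 not past (camera adjusted p = 0.0022; adjusted p = 0.199 with an estimated correlation). The peptide hormone gene ADM was higher by 2.13 ± 0.24 and the glucose transporter SLC2A3 by 2.55 ± 0.35.

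**Figure D2:**
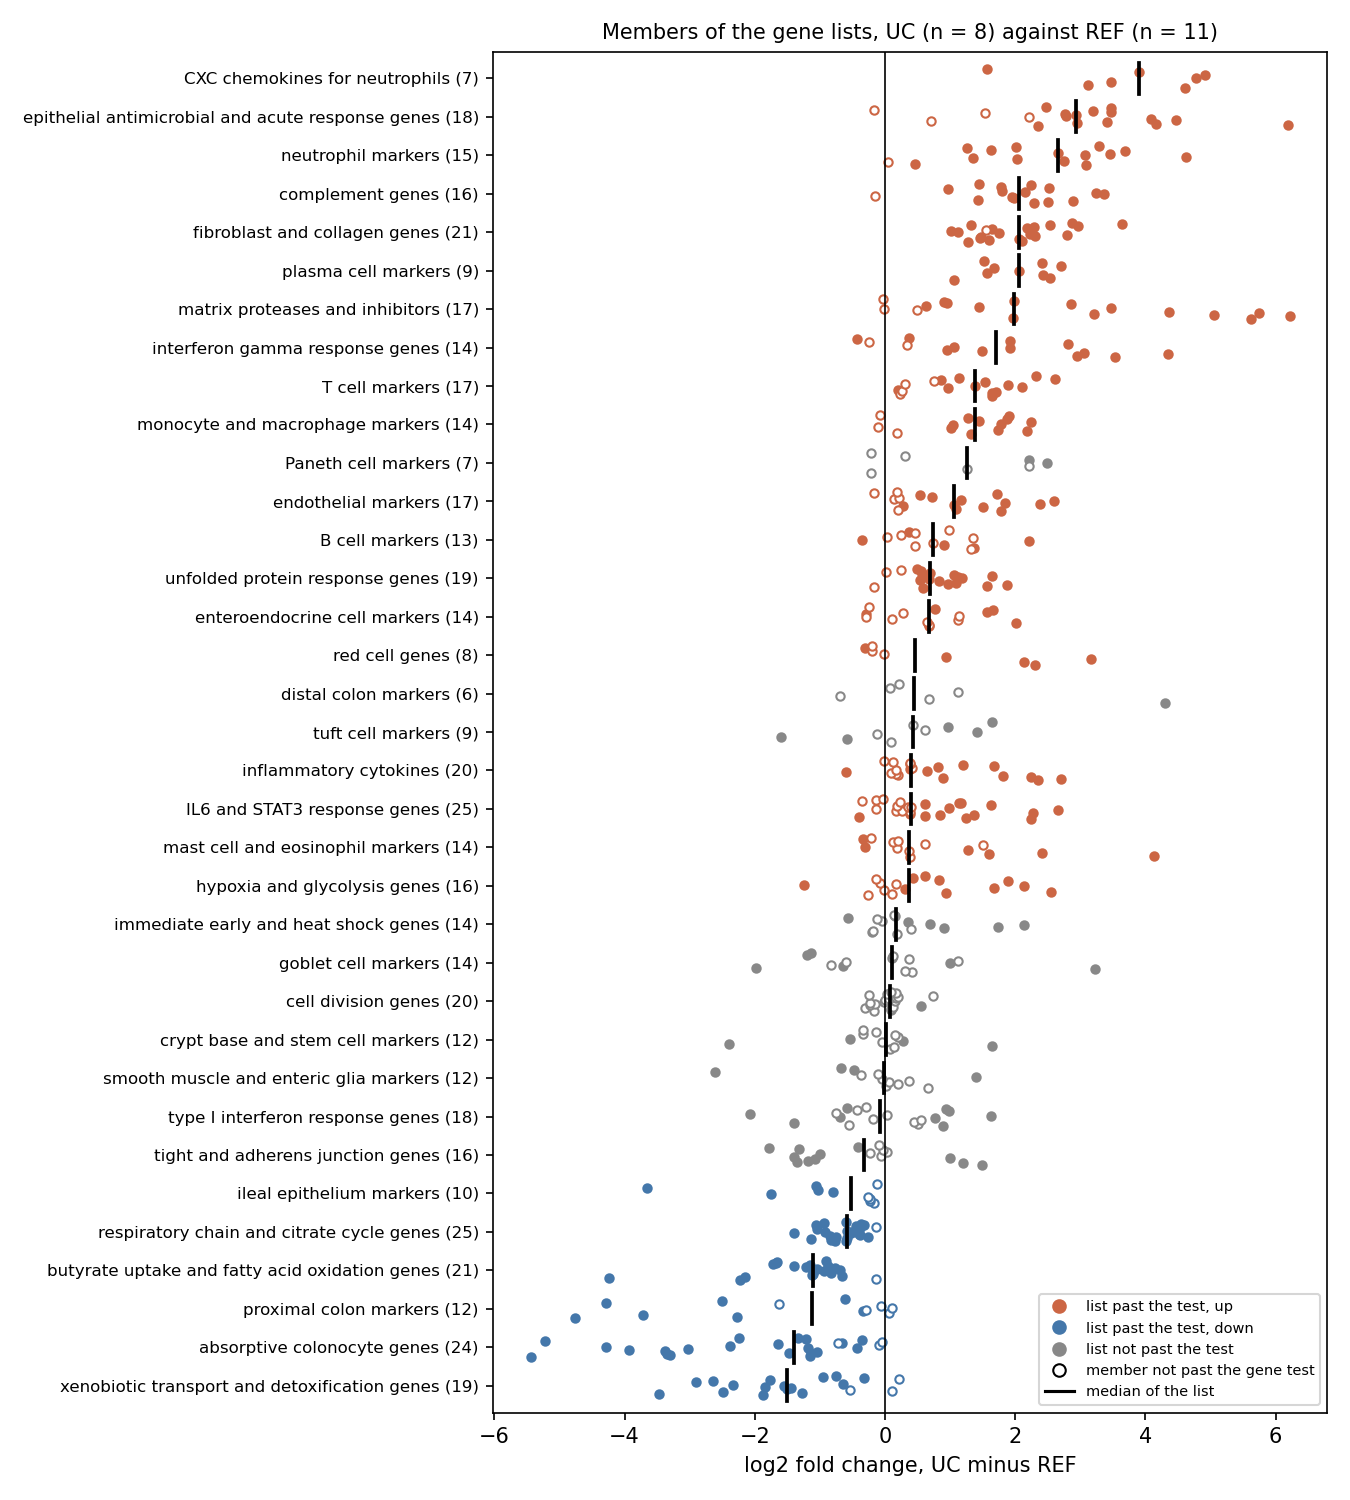
Log2 fold change, UC minus REF, of each measured member of the 35 gene lists, ordered by the list's median (black line), with the number of members in brackets; filled points passed the gene test, and colours show whether camera called the list up, down or not at all. The medians run from 3.90 for the CXC chemokines to -1.51 for the xenobiotic genes.

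Markers of the other epithelial types moved both ways. Of 14 goblet cell markers 2 were higher, 4 were lower and 8 did not pass (camera adjusted p = 0.60), or 2 and 3 adjusted over the list alone. SPINK4, a secreted goblet cell peptide, was higher by 3.23 ± 0.56 and above every REF array in 8 of 8 UC arrays, whereas ZG16, chosen after its value was seen, fell by 1.98 ± 0.48. Of 9 tuft cell markers 3 were higher and 2 were lower, with AVIL 3.03-fold lower (camera adjusted p = 0.24; adjusted p = 0.53 with an estimated correlation). With REF 4, 5 and 6 left out, an alternative chosen after seeing the data, that list passed at the preset correlation (adjusted p = 0.044). PTGS1 and ALOX5, chosen after their values were seen, rose and are also expressed by leukocytes. Of 12 crypt base and stem cell markers 2 were higher and 2 lower, or 1 and 1 adjusted over the list alone. That list had a median of 0.02, a mean of -0.11 and an upward camera direction (adjusted p = 0.51). SMOC2 was higher by 1.64 ± 0.26. Of 20 cell division genes 1 passed, BUB1 at 0.55 ± 0.18, and 0 adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.32). Of 14 enteroendocrine markers 4 were higher, 1 was lower and 9 did not pass, with the granule protein SCG5 at 1.67 ± 0.39 and the transcription factor ISL1 at 1.57 ± 0.41 (0.53 with PRAC1 as a covariate). The enteroendocrine call (camera adjusted p = 0.041; adjusted p = 0.44 with an estimated correlation) was lost with quantile normalization (adjusted p = 0.074), median centring (0.098), array weights (0.063), numbers 1 to 8 without the block (0.0527), fry (0.107), REF 7, 8 and 9 left out (0.0795) and PRAC1 as a covariate (0.19). It was also lost without REF 1, 8 or 10 or UC 1, 6 or 7, each left out alone (adjusted p from 0.0515 to 0.0706). Of 16 tight and adherens junction genes 3 were higher and 8 lower, a mixture that did not pass camera (adjusted p = 0.16) and passed the self-contained test fry downward (adjusted p = 0.0073). MARVELD3, a tight junction membrane protein, fell by 1.78 ± 0.21. The claudins CLDN1 and CLDN2, chosen after their values were seen, rose by 1.49 ± 0.27 and 1.20 ± 0.29, while CLDN3 fell by 1.34 ± 0.24.

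Some markers of the colon segment differed between the groups. Of 12 proximal colon markers 7 were lower and 5 did not pass, with a median of -1.13, and GBA3, a cytosolic beta-glucosidase, fell by 3.72 ± 0.67, or by 1.87 with PRAC1 as a covariate. GBA3 ran from -1.71 to 1.06 on the log2 scale over the REF arrays, from -4.02 to -1.17 in UC 1 to 4 and from -6.60 to -4.80 in UC 5 to 8. The proximal list mean split there too (-2.04 to -0.86 against -3.01 to -2.43), as did ANPEP (-2.85 to -2.26 against -6.09 to -4.73). SLC51A stood at the lower limit in UC 5 to 8 only, whereas ETNK1 overlapped. This split was chosen after the values were seen and its source was not tested. A fold over all UC arrays averages over it. Of 6 distal colon markers 1 passed, PRAC1, which was higher in UC by 4.30 ± 1.32 (adjusted p = 0.012), and the list did not pass (adjusted p = 0.29). The log2 fold change of PRAC1 was 3.67 without UC 6, 3.72 without UC 7, 5.12 over numbers 1 to 8 with or without the block and 5.04 with REF 4, 5 and 6 left out. PRAC1 lost its call with quantile normalization (adjusted p = 0.061), and ran from -5.21 to 2.42 over the REF arrays. The proximal list was called downward (camera adjusted p = 0.041; adjusted p = 0.40 with an estimated correlation), but not with PRAC1 as a covariate (median -0.20, adjusted p = 0.23). That call was also lost with a trended and robust variance prior (adjusted p = 0.157), with genes of several lists left out (0.079), with REF 4, 5 and 6 left out (0.080), and without REF 1, 2, 4, 6 or 8 or UC 6, 7 or 8, each left out alone (adjusted p from 0.0508 to 0.0632). Of 10 ileal epithelium markers 5 were lower, 7 adjusted over the list alone, led by the aminopeptidase ANPEP, down by 3.65 ± 0.61 (2.10 with PRAC1 as a covariate), and the alkaline phosphatase ALPI, down by 1.02 ± 0.18 (camera adjusted p = 0.021; adjusted p = 0.183 with an estimated correlation).

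**Figure D3:**
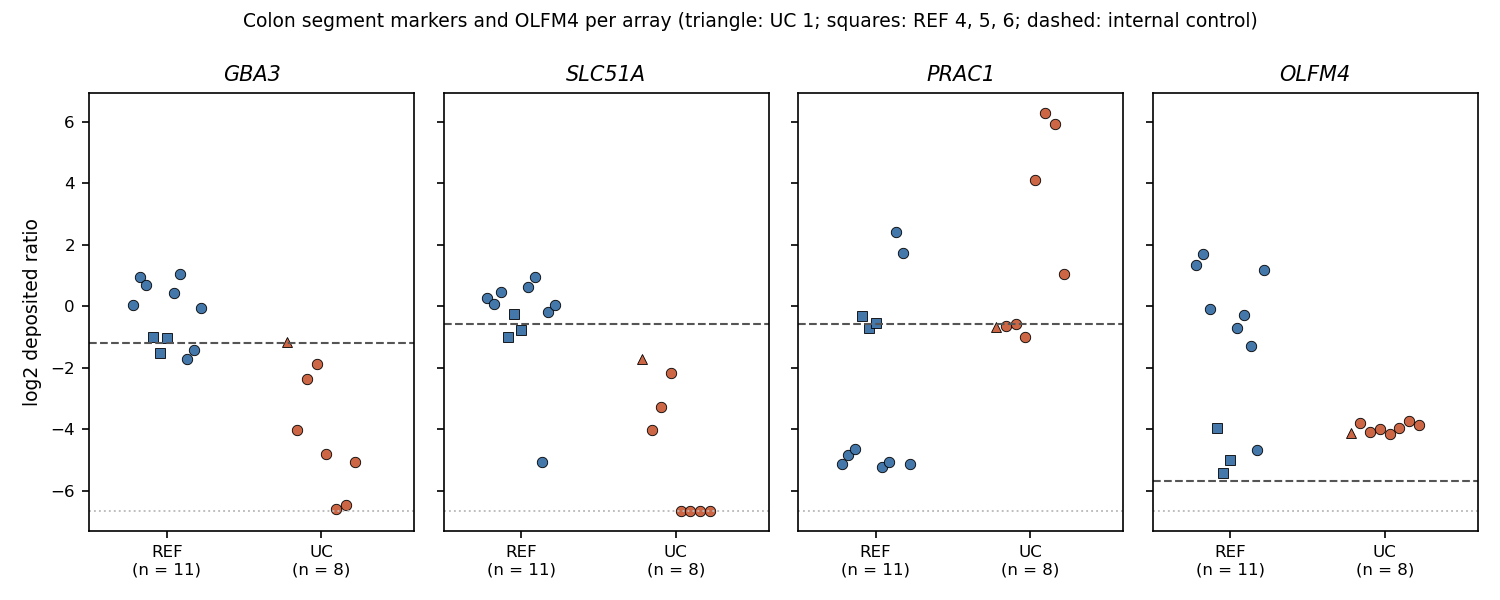
Log2 ratio per array of GBA3 and SLC51A (proximal colon markers), PRAC1 (a distal marker) and OLFM4 (a crypt base marker chosen after its values were seen) in REF (blue, n = 11) and UC (orange, n = 8), with the internal control as a dashed line and the lower limit dotted; triangles are UC 1 and squares REF 4, 5 and 6. GBA3 lay at or below -1.17 in all UC arrays, and PRAC1 ran from -0.99 to 6.27 in UC and from -5.21 to 2.42 in REF.

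Genes that follow tissue handling were also compared. Of 14 immediate early and heat shock genes 5 were higher, 1 was lower and 8 did not pass (camera adjusted p = 0.062; adjusted p = 0.27 with an estimated correlation), with the transcription factor EGR2 higher by 1.73 ± 0.27. That list passed when REF 8, UC 2, UC 3 or UC 5 was left out alone (adjusted p from 0.0215 to 0.0492), and with array weights (0.023), the replicate block (0.0498), fry (0.025) or REF 7, 8 and 9 left out (0.0107). Of 8 red cell genes 4 were higher, all of them globins, and 1 was lower. HBA1 was higher by 2.30 ± 0.35 and HBA2 by 2.14 ± 0.33. The red cell call (camera adjusted p = 0.048; adjusted p = 0.171 with an estimated correlation) was lost with median centring (adjusted p = 0.058), a trended and robust variance prior (0.0502), REF 4, 5 and 6 left out (0.080), and without REF 1, 2, 3, 4, 5 or 6 or UC 6, each left out alone (adjusted p from 0.0508 to 0.0713).

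Across the 35 lists 19 were called upward and 6 downward by camera with a preset correlation of 0.01, and 0 with an estimated correlation, where 13 had an unadjusted p under 0.05 and the lowest adjusted p was 0.117. The self-contained test fry called 25. Of 100 splits of the same arrays into groups of the same sizes, the real one included, 8 gave as many camera calls as the real split. For 25 lists the member counts were the same adjusted over the list alone, and the other 10 are given above.

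The spread within groups was wider in REF than in UC. The median standard deviation per probe set was 0.31 on the log2 scale over the 11 REF arrays and 0.20 over the 8 UC arrays. The 4 Internal Control columns held the same values, with a median standard deviation of 0, so they carry no measure of technical error. REF 4, 5 and 6 lay nearest to UC, with correlations of 0.60, 0.61 and 0.62 over probe sets with the mean of the UC arrays, where REF 7, 8 and 9 had -0.58, -0.51 and -0.47. Because the REF mean of each probe set is set to 1, positive correlations in some REF arrays bring negative ones in others. The negative sign alone therefore does not mean a state opposite to UC.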

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

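The tests of the proximal markers, of the immune and stromal list pairs and of the internal control reading were chosen only after the result was seen, as were the test of the absorptive and butyrate genes and PRAC1 as a covariate. Among the 8 UC arrays, 64 gene values and 35 list scores were tested for 1 array far from the others, by its gap to the nearest array over the range of the group, and 10 passed Dixon's limit, where chance passes about 1 in 20. REF, with 11 arrays, was not tested. In 9 of the 10 the array was UC 1, which lay nearest to REF each time. MMP3, MMP10 and TIMP1 also belong to the flagged matrix protease list, so the flags are not separate tests. UC 1 was not near REF throughout. IFNG, picked here after its values were seen, stood at 3.19 in UC 1 and between 0.74 and 2.32 in the other UC arrays. The ratio of gap to range was 0.817 for SLC6A14, 0.817 for MMP3, 0.574 for DUOX2, 0.663 for MMP10, 0.607 for PCK1, 0.626 for TIMP1 and 0.662 for FKBP11. It was 0.643 for the mean of the matrix protease list and 0.610 for that of the butyrate list. MMP10 stood at 0.51 in UC 1 and between 5.15 and 7.51 in the other UC arrays. The remaining one was EGR2 in UC 2, with a ratio of 0.581 and a log2 value of 2.40, where the other UC arrays lay between 1.24 and 1.72. Over all probe sets UC 1 correlated at 0.75 with the mean of the other UC arrays, and the others at 0.87 to 0.93.

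Proximal colon markers were among the strongest decreases in UC, and absorptive and butyrate genes fell too. The mean score of the 12 measured proximal markers was -1.69 ± 0.37 (SE) in UC against REF and -0.66 ± 0.19 with PRAC1 as a covariate (95% interval -1.06 to -0.27), and a median of 52.7% of the log2 fold change remained over the 7 called ones (quartiles 51.4 to 55.8, 4 calls kept), so for these segment and UC cannot be told apart without the segment of the REF biopsies. The score of the 45 absorptive and butyrate genes went from -1.70 ± 0.18 to -1.54 ± 0.22 (95% interval up to -1.08), with a median of 85.8% remaining over the 41 called ones (quartiles 71.9 to 99.9, 35 calls kept). Within REF the slope of that score on PRAC1 was -0.026 ± 0.026. PRAC1 lay near the Internal Control (-0.57) in REF 4 to 6 and UC 1 to 4, so it may follow more than segment. For the absorptive and butyrate genes the values argue against the difference that PRAC1 follows, whatever its source, as the whole cause. They cannot argue against a segment or batch difference that PRAC1 does not follow. The limit for that verdict, an interval beyond 50% of the first difference, was set after these values were seen. It replaced others, of which a lower quartile over 80% gave no verdict. A covariate removes only what follows that gene, and PRAC1 is the milder of 2 tried, so a segment difference may account for a larger part of both falls than these shares show.

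Immune and stromal markers were higher in UC, and a lower share of epithelium would raise such markers alike only where all are measured well. Of the 28 pairs of 8 immune and stromal lists, 16 shifted by different amounts (permutation test of the arrays, adjusted p under 0.05). The lists also hold members that did not pass, such as CXCR1 (0.04) and CD68 (0.19), and dim probe sets could not be recognised. Unequal list means therefore cannot decide whether a lower epithelial share is the whole cause. The list means rose most for neutrophil markers (2.36), fibroblast genes (2.01) and plasma cell markers (1.99), and least for B cell (0.78) and mast cell markers (0.85). A lower epithelial share stays open. More cells of the types that rose, and a change of expression within cells in UC, both stay open as untested.

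REF 4, 5 and 6 lay nearer to the UC arrays than the other REF arrays did. Whether these 3 biopsies held more lamina propria stays open: removing the mean score of the immune and stromal lists within REF lowered their mean correlation from 0.81 to 0.17, but also from 0.56 to 0.14 over the least variable probe sets, so it takes away whatever the 3 arrays share and decides nothing. Against the other REF arrays their list means were higher by 1.42 for monocyte, 1.41 for mast cell and 1.21 for plasma cell markers, but by 0.40 for neutrophil and 0.18 for endothelial markers. At 2549 probe sets the 3 arrays lay within the UC range and outside that of the other REF arrays, where the highest of all other sets of 3 REF arrays gave 945 and the median set 39. That count is what another internal control reading in their batch would leave, and also what a difference between the biopsies, colon segment included, would leave, and the 2 cannot be told apart without the batch of each array.

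Of 100 splits of the 19 arrays into 11 and 8, 1, the real one, reached its count of probe sets (13183, highest other 11118), 1 its count at 2-fold (2833, highest other 2414) and 1 its count of genes (8206, highest other 6962), so chance is unlikely to give these counts. The splits cannot separate UC from a batch or a colon segment that follows the group labels. The highest other split held 7 of the 8 real UC arrays on 1 side, and 97 splits called 0 probe sets. For the list count (25, highest other 29) 8 of the 100 splits reached the real one, so chance cannot be excluded for that count alone. The random splits called a median of 16 lists, which points to a structure among the arrays that the preset correlation does not cover.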

How the results depend on the processing

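The alternatives with PRAC1 as a covariate, with REF 4, 5 and 6 or REF 7, 8 and 9 left out, and with the arrays numbered 1 to 8 without the block were chosen after seeing the data. Quantile normalization lowered the probe sets from 13183 to 4929 (48.5% lower in UC, against 65.2%), those at 2-fold from 2833 to 1206 and the genes from 8206 to 3279, of which 3269 were among the original calls. With PRAC1 as a covariate the counts were 7684, 2351 and 4899. A limit of 1.5-fold gave 5997 probe sets by its own construction, and an estimated correlation left 0 lists (13 at an unadjusted p under 0.05, 25 by fry). Quantile normalization gives every array the same distribution. The standard deviation over probe sets was 0.29 to 0.68 in REF arrays and 0.50 to 0.90 in UC arrays. Smaller folds in UC therefore follow in part from the method. How much of the fall in counts this explains was not tested, nor was the cause of the PRAC1 changes. With PRAC1 the median standard error rose from 0.14 to 0.17 over all called genes and fell from 0.54 to 0.45 over the proximal markers. Leaving out 1 array gave 11675 to 13939 probe sets, 2588 to 3131 at 2-fold, 7275 to 8627 genes and 22 to 26 lists. Every other alternative stayed within 1.5 times the counts of probe sets, genes and lists, among them 15354 and 10668 probe sets without REF 4, 5 and 6 and without REF 7, 8 and 9. The direction of these last changes follows from the choice of the arrays nearest to and farthest from UC, so they are no independent check. Named genes gave 1216 of 1216 values with the same call on leaving out 1 array, and 501 of 511 under the other alternatives, with 10 calls lost. Lists gave 640 of 665 and 403 of 455, with 21 and 45 calls lost and 4 and 7 gained. The arrays carry no signal over background here, so what dim probe sets limit is unknown.

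Same-numbered REF and UC arrays did not deviate together (correlations of -0.23 to 0.08, 0 of 8 pairs over 0.1, and 0 pairs in which each array correlated best with its own number), so the numbers do not pair the arrays. The fit with the replicate block gave 9605 probe sets, 2510 at 2-fold, 5911 genes and 26 lists, against 11614, 2538, 7197 and 24 for the same arrays without it.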

Other observations

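Genes outside the lists, all chosen after their values were seen, extended the account of UC tissue. CHI3L1, a chitinase-like glycoprotein, was higher by log2 4.92 ± 0.55 (SE), IL13RA2, a decoy receptor of interleukin 13, by 3.96 ± 0.61 and PROK2, a prokineticin, by 3.93 ± 0.55, each above every REF array in 7 of 8 UC arrays. The matricellular protein gene CCN1 (4.13 ± 0.49) and GREM1, an antagonist of bone morphogenetic proteins (4.09 ± 0.57), lay above every REF array in 8 of 8. TDO2, a tryptophan dioxygenase, rose by 3.85 ± 0.70 and KYNU, a kynureninase, by 2.81 ± 0.34. So did the prostaglandin synthase PTGS2 (3.46 ± 0.42), the cholesterol 25-hydroxylase CH25H (3.89 ± 0.61) and the prohormone convertase PCSK1 (3.75 ± 0.41). The chemokines CCL2 and CCL11 rose by 3.13 ± 0.54 and 2.74 ± 0.43.

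Other genes outside the lists, chosen in the same way, fell. The vitamin C transporter SLC23A1 fell by 3.31 ± 0.41, the related SLC23A3 fell by 3.45 ± 0.42 and SLC17A4 fell by 3.00 ± 0.22, each below every REF array in 8 of 8 UC arrays. The amino acid transporter subunit SLC3A1 fell by 2.78 ± 0.34, the creatine kinase CKB fell by 2.89 ± 0.40 and LAMA1, a laminin chain, fell by 3.08 ± 0.41. APOBEC3B, a cytidine deaminase, fell by 2.81 ± 0.35.

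OLFM4, a crypt base gene chosen after its values were seen, lay between -4.16 and -3.74 in the UC arrays (SD 0.15, n = 8) and between -5.42 and 1.70 in the REF arrays (SD 2.71, n = 11). Its mean was lower in UC by 2.40 ± 0.89 (limma adjusted p = 0.0315), but the REF arrays were split. OLFM4 stood at -3.96, -5.42, -4.99 and -4.67 in REF 4, 5, 6 and 10, and between -1.30 and 1.70 in the other REF arrays. No UC array lay below all REF arrays. The Internal Control stood at -5.68. PRAC1 lay between -0.99 and -0.58 in UC 1 to 4, at 4.12, 6.27, 5.92 and 1.04 in UC 5 to 8, at -0.33, -0.71 and -0.54 in REF 4 to 6, at 2.42 and 1.75 in REF 9 and 10, and at -0.57 in the Internal Control. The standard deviation was larger in REF than in UC for 12639 of 15948 genes, with a median log2 ratio of UC over REF of -0.63.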
